A study of Rattus norvegicus and Homo sapiens with 11 samples.

How the data were processed

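The series has 11 arrays in 2 arms. In the rat arm, small RNA of the dorsal striatum of male Wistar rats was profiled on 9 one-colour microRNA arrays, 3 per group. The groups were cocaine-naive controls, rats with restricted access (1 h per day) and rats with extended access (6 h per day) to intravenous cocaine at 0.5 mg/kg per infusion over 7 days. Tissue was taken 24 h after the last session. Each group had 6 rats, and each array carried RNA pooled from 2 of them, so the 3 arrays of a group came from different animals. In the human arm, cells of an established human embryonic kidney (HEK) line received an empty vector or a vector expressing the miR-212 precursor transcript, and 1 Affymetrix array was run per condition.

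Per the labels' protocols, rat small RNAs were labelled at the 3' end with the Oyster-550 dye, and HEK complementary RNA carried biotin (1 µg of total RNA at the start, 20 µg of product hybridised). Per the file headers, the deposited scanner files of the rat arm hold spot intensity as pixel medians at 532 nm with a local background, read by GenePix Pro 4.1.1.44 and not normalized. The 3 scanner files of a group were identical and covered a whole slide of 6 slots, of which 3 belonged to that group's samples. A sample's slot was therefore found by matching its named column of the deposited matrix of background-subtracted intensity with the 6 slots. At the matching slot all 474 deposited spot values were equal (473 of 473 for extended replicate 2), against at most 31 in the next best slot. Over the 3 slides, 9 slots belonged to no sample here and were not used. Each group lay on a slide of its own, with control and restricted samples in slots 1, 3 and 5 and extended samples in slots 2, 4 and 6, so slide and group cannot be told apart. The deposited value table of the rat arm held a ratio of each spot to 1 factor of its own for all 9 arrays. Within a relative tolerance of 0.02 this held for 388 of 474 table entries with the same spot and for the other 86 with the probe's other spot, and 42 values stood at the floor of 0.01. The column medians of that table were 0.821, 0.760 and 0.929 for control, 1.00, 1.13 and 1.16 for restricted and 1.00, 1.04 and 1.00 for extended samples. How the authors set the factor of dim spots is not given in the sources used here. For the HEK arm, the authors' deposited table gives linear probe set intensity on both arrays and the ratio of miR-212 over empty vector, and marks probe sets with an empty vector signal under 100 as left out. RMA and GCRMA are named in the submitters' processing notes without a role.

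Rat intensities were background corrected with limma's normexp (offset 50), quantile normalized over all spots of the 9 arrays and averaged on the log2 scale over the 2 spots of each probe, in R 4.3.3 with limma 3.58.1. The pixel median replaced the planned pixel mean, because the scanner files used here give medians. Control, blank and numbered probes (816 probes without a microRNA name) stayed out of the tests. A probe counted as above background on an array where its foreground exceeded the local background by 2 SD of the background pixels in both of its spots. Of 237 rat probes, 151 met this on at least 3 arrays and were tested, 128 met it on all 9 arrays and 78 on none. Spots that the scanner had flagged were kept. Among spots of tested probes these were 5 with flag -50 and 1 with flag -100.

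The 3 contrasts and an F test over the groups were fitted with limma (lmFit, eBayes) on all 9 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. Over the 3 groups, miR-212 and miR-132 were also tested by two-sided exact permutation of an F statistic and of a Jonckheere trend statistic (1680 assignments, 4 tests in the family). With 3 arrays against 3, an exact permutation test cannot give a p below 0.1. Of 15 microRNA lists, 12 had at least 3 measured members and were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry. List members were matched to probes by name. The measured probes miR-146 and miR-92 therefore entered no list, although miR-146a, miR-146b and miR-92a were listed. Counts of list members leave these probes out. The designs, lists and rule for named microRNAs were fixed before the data were examined. That rule took miR-212 and miR-132, the microRNAs past the threshold without overlap between groups, otherwise those with the lowest unadjusted p up to 10 per contrast, and the 2 members of each list with the largest difference. For HEK cells the rule named genes. The files used here do not pair probe sets with genes, so counts are of probe sets, 4 probe sets with the most extreme ratios are given by their values, and the HEK gene lists and named genes were not analysed here. With 1 array per condition, HEK ratios carry no error and no test.

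The procedure was tested on simulated data for extended against control with 151 probes, over 100 simulations with 10 probes changed at each fold. It recovered 77% of probes changed 1.4-fold, 88.9% at 1.5-fold and 99.5% at 2-fold, with 1.18 false calls among 27.7 calls per simulation. These shares depend on the simulated spread and on the number of changed probes. With fewer changed probes the Benjamini-Hochberg adjustment is stricter, and no slide difference was simulated. The shares may therefore overstate what the real arrays recover. Alternatives covered the background correction, the normalization, the filter on dim probes, the value source, the replicate number as a block, eBayes with a trend, the arrays fitted and leaving out each array. HEK alternatives covered the signal filter, the fold, centring and the value table. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.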

Results

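MicroRNAs of the dorsal striatum were measured in cocaine-naive rats and in rats with restricted (1 h per day) or extended (6 h per day) access to self-administered cocaine, with 3 arrays per group and RNA of 2 rats on each array. The arrays had between 136 and 154 of the 237 rat microRNA probes above background, and 0% of the negative control spots on any array. After normalization, pairs of arrays correlated across probes at 0.988 to 0.998 within groups and at 0.986 to 0.996 between groups. The median difference between the 2 spots of a probe was 0.15 to 0.33 (log2) per array. Before normalization the arrays differed in brightness. The median log2 intensity of the probes above background on all arrays averaged 9.38 in control, 9.82 in restricted and 9.63 in extended arrays. The median difference over the 151 tested probes was 0.44 for restricted and 0.26 for extended against control arrays. All differences below are relative to that array-wide level, which quantile normalization removed. The number of arrays limits the precision: the median standard error of a difference was 0.12 (log2), and of 97 differences of named microRNAs 18 turned and 37 others moved by over 1.5 times when 1 array was left out.

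**Figure D1:**
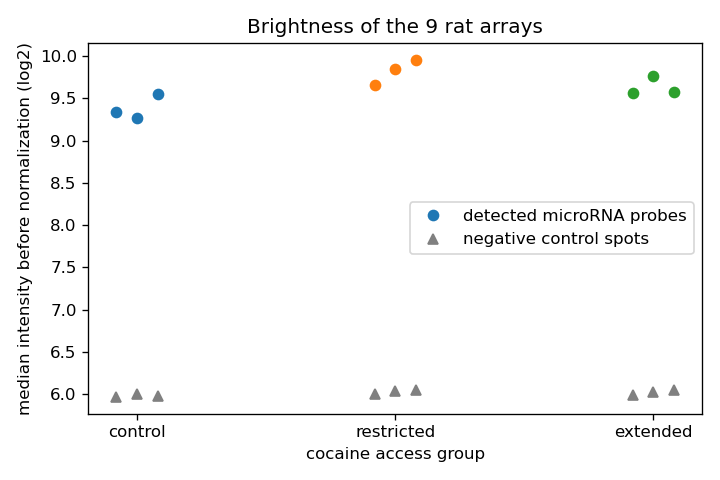
Median log2 intensity after background correction and before normalization (vertical axis) of detected microRNA probes (circles) and negative control spots (triangles) on each of the 9 rat arrays, by cocaine access group (horizontal axis). The group means of the circles are 9.38, 9.82 and 9.63 for control, restricted and extended arrays, while those of the triangles are 5.98, 6.03 and 6.02.

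The first question was how miR-212 and miR-132, neighbours in 1 activity-regulated cluster, differed with the extent of cocaine access. Normalized miR-212 was 10.75 ± 0.08 (log2, SD, n = 3) in control, 10.52 ± 0.17 in restricted and 11.24 ± 0.27 in extended arrays. Its lowest extended array, at 11.06, lay above the highest control array, at 10.84, and above the highest restricted array, at 10.71. MiR-132 was 12.34 ± 0.21 in control, 12.44 ± 0.22 in restricted and 12.82 ± 0.12 in extended arrays (log2, SD, n = 3). MiR-212 and miR-132 were picked because the human arm of this series overexpresses miR-212, so their choice may not be independent of these arrays. For miR-212 the groups differed by an exact permutation test of the F statistic over 9 arrays (p = 0.00357, the smallest it can give, and 0.0143 adjusted over 4 tests). Over all 151 probes the smallest adjusted p of that test was 0.270. With the replicate number as a block, the exact F test of miR-212 gave p = 0.0278 (0.0556 adjusted over 4 tests). Its exact trend test gave p = 0.344, and 0.00357 (0.0143 adjusted over 4 tests) both without normalization and with the value table, where the restricted mean lay above the control mean. For miR-132 the exact permutation p was 0.0821 for the F statistic and 0.0738 for the trend (both 0.110 adjusted over 4 tests). For miR-132 the extended arrays exceeded the mean of the other groups by 0.28 (SE 0.25) at its first spot and by 0.57 (SE 0.14) at its second, and for miR-212 by 0.55 (SE 0.13) and 0.67 (SE 0.14). Extended arrays shared a slide and a set of slots that held no other group, so slide and access cannot be told apart.

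**Figure D2:**
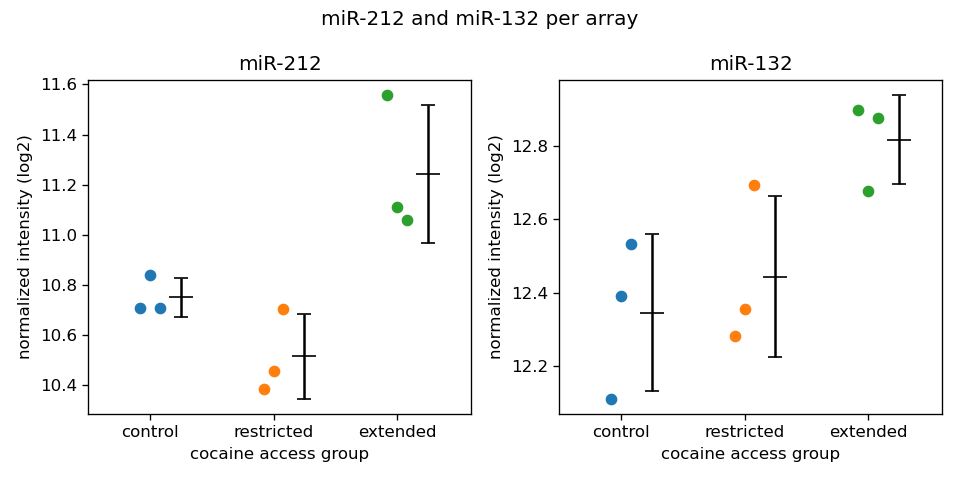
Normalized log2 intensity (vertical axis) of miR-212 and miR-132 on each array (points), with the group mean and SD over 3 arrays (bar and whiskers), by cocaine access group (horizontal axis). Extended arrays average 11.24 for miR-212 and 12.82 for miR-132, against 10.75 and 12.34 in control arrays.

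In extended against control rats, miR-212 was 1.41-fold higher (log2 difference 0.49, SE 0.14, and 0.32 without extended replicate 1) and miR-132 was 1.39-fold higher (0.47, SE 0.14), each on 3 of 3 extended arrays above all control arrays. Neither passed limma's threshold over all 151 probes (adjusted p = 0.321 for each), while 2 of 2 passed when adjusted over the list alone. That list was picked through the human arm of this series. The neuronal miR-137 differed by 0.45 (SE 0.13) and miR-352 by 0.44 (SE 0.14), with the same limma adjusted p of 0.321. Limma called 0 of the 151 microRNAs, with 10 at an unadjusted p under 0.05 (8 higher, 2 lower) where chance gives 7.55. The 2 groups did not overlap for 10 microRNAs, or 6.62%, beside the 10% that chance gives. Other microRNAs with low unadjusted p were miR-7 at 0.24, miR-323 at 0.33, let-7f at 0.32, miR-139 at 0.24, miR-383 at -0.44 (0.024 from its first spot alone) and miR-222 at -0.30. MiR-7 was above background on 2 of 3 extended arrays. Among neuron-enriched microRNAs, 11 of 14 were positive, with miR-137 and miR-383 the most different, and 3 had an unadjusted p under 0.05. Of the imprinted miR-379 to miR-410 cluster, 16 of 20 members were positive, led by miR-323, with miR-382 at -0.27. The let-7 family had 6 of 9 positive members, with let-7c at 0.56 (0.36 without extended replicate 1, and 0.95 and 0.17 from its first and second spots) and let-7b at 0.34 (0.19 without extended replicate 3). MicroRNAs linked to cocaine in earlier work had 4 of 12 positive members, with miR-222 at -0.30 and miR-29b at -0.16. The miR-29 family had 0 of 4 positive members, with miR-29a at -0.10. In the miR-30 family 2 of 5 were positive (miR-30b at -0.29, miR-30d at 0.21, or 0.41 without control replicate 1, 0.018 without control replicate 2 and 0.11 without extended replicate 2), in the miR-17/92 clusters 2 of 7 (miR-20a at -0.17, miR-93 at 0.06), and among synaptic plasticity microRNAs 2 of 9 (miR-125b at 0.17).

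Markers of other cell types in the same comparison included oligodendrocyte microRNAs with 3 of 4 positive (miR-219 at 0.10, miR-23b at -0.08) and microglia and leukocyte microRNAs with 2 of 4 (miR-223 at 0.08, miR-21 at 0.07). For both lists camera gave a lower direction while the median and mean were above 0. Vessel wall microRNAs had 1 of 4 positive (miR-24 and miR-145 at -0.06 each) and choroid plexus and ependyma microRNAs 3 of 3 (miR-34c at 0.12, miR-204 at 0.03). Below the size for a list test, the red blood cell microRNAs miR-451 and miR-16 differed by 0.07 and -0.01. Of the muscle and liver list, only miR-194 and miR-192 were measured, at -0.13 and -0.0048. Its muscle members, such as miR-1 and miR-133a, and miR-122a were too dim to test. Both miR-223 and miR-451 were above background on 1 of 3 control, 3 of 3 restricted and 1 of 3 extended arrays. Detection was judged before normalization, when restricted arrays were brighter. Adjusted over the list alone, 0 members of any of the 12 tested lists passed, as over all 151 probes. Camera called 0 of 12 lists (1 at an unadjusted p under 0.05, smallest adjusted p = 0.346, and 0.518 with an estimated correlation) and fry called 0 (smallest adjusted p = 0.341).

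In restricted against control rats, miR-218, a neuronal microRNA, differed by -0.43 (SE 0.11) and miR-330 by 0.46 (SE 0.13), each with a limma adjusted p of 0.339. Let-7c differed by 0.71 (SE 0.26), neuronal miR-124a by 0.53 (SE 0.20) and miR-30d by 0.47 (SE 0.18), again at a limma adjusted p of 0.339. MiR-212 differed by -0.23 (SE 0.14, limma adjusted p = 0.459), turning to 0.26 without normalization and 0.27 with the value table, and miR-132 by 0.10 (SE 0.14, limma adjusted p = 0.763), turning to -0.03 when arrays were scaled to their 75th percentile. Limma called 0 of 151 microRNAs, with 19 at an unadjusted p under 0.05 (11 higher, 8 lower) where chance gives 7.55. Groups were apart without overlap for 20 microRNAs, or 13.2%, beside the 10% that chance gives. These counts, too, cannot tell slide and access apart, as each group lay on its own slide. Further microRNAs with low unadjusted p were miR-222 at -0.38, miR-129* at 0.28, miR-324-5p at 0.41 and miR-664 at -0.26. MiR-494 was above background on 3 of 3 restricted arrays and on 0 of 3 control and 0 of 3 extended arrays. Detection was judged before normalization, when restricted arrays were brighter, so this split cannot be told apart from array brightness. For restricted against control, the fitted difference of miR-494 was 0.23 (SE 0.08, limma adjusted p = 0.339), and -0.21 after 75th percentile scaling. With control values raised to the lowest detected signal the fold was 1.07, which is not a minimum. Undetected extended values averaged 6.67 before and after the same step, so that signal is no upper limit. Without control replicate 1, limma called 10 microRNAs, among them miR-124a at 0.78, miR-30d at 0.67, miR-324-5p at 0.60 and miR-218 at -0.48. Without control replicate 2 limma called 0 (5 at an unadjusted p under 0.05), with miR-124a at 0.31 and miR-30d at 0.28.

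By list, neuron-enriched microRNAs in restricted rats had 6 of 14 positive members (4 at an unadjusted p under 0.05), led by miR-124a and miR-218, with a median below and a mean above 0. Of these 1 passed when adjusted over the list alone, and 0 over all 151 probes. The let-7 family had 6 of 9 positive (let-7c and let-7i at 0.71 each), the miR-379 to miR-410 cluster 12 of 20 (miR-329 at 0.28) and the miR-17/92 clusters 5 of 7 (miR-93 at 0.35, or 0.57 without control replicate 1 and 0.18 without control replicate 2, miR-25 at -0.15, or -0.27 without control replicate 1, -0.0024 without control replicate 3 and -0.059 without restricted replicate 1). The miR-92 probe, left out of the miR-17/92 list by its name, read 8.54 to 8.92 (log2) on restricted and 8.83 to 9.09 on control arrays. Of microRNAs linked to cocaine in earlier work, 2 of 12 were positive, with miR-124a at 0.53 and miR-222 at -0.38. The miR-29 family had 1 of 4 positive (miR-29c at -0.21, miR-29a at -0.10, the same as in extended rats because quantile normalization hands these very bright probes few values), and synaptic plasticity microRNAs 3 of 9 (miR-9 at -0.26, miR-125b at 0.26). In the miR-30 family 2 of 5 were positive, with miR-30d at 0.47 and miR-30a-3p at -0.20, and the median was below while the mean was above 0. Oligodendrocyte microRNAs had 3 of 4 positive (miR-338 at 0.34, miR-219 at 0.32), vessel wall microRNAs 2 of 4 (miR-126 at 0.52, miR-143 at 0.21), microglia and leukocyte microRNAs 0 of 4 (miR-223 and miR-150 at -0.16 each) and choroid plexus and ependyma microRNAs 0 of 3 (miR-204 at -0.24, miR-34c at -0.16). The miR-146 probe, left out of the microglia and leukocyte list by its name, went the other way. It read 8.52 to 8.64 (log2) on restricted and 8.08 to 8.48 on control arrays. Untested for size, miR-451 and miR-16 differed by 0.13 and 0.04, and miR-194 and miR-192 by 0.10 and -0.09. Camera called 0 of 12 lists (2 at an unadjusted p under 0.05, smallest adjusted p = 0.233, and 0.700 with an estimated correlation) and fry called 0 (smallest adjusted p = 0.173).

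Between extended and restricted rats, miR-212 had the largest difference of the 151 microRNAs, 1.66-fold higher with extended access (log2 0.73, SE 0.14), with 3 of 3 extended above all restricted arrays. Its limma adjusted p was 0.0674, short of the threshold. It passed at 0.00627 after 75th percentile scaling and at 0.0385 with eBayes's trend and robust options, over a range of 0.00627 to 0.337 across alternatives. MiR-7, a neuronal and neuroendocrine microRNA, was 0.41 higher (SE 0.09, limma adjusted p = 0.0779). MiR-664 at 0.43 (SE 0.10), miR-218 at 0.44 (SE 0.11) and miR-383 at -0.67 (SE 0.17) shared a limma adjusted p of 0.0841. MiR-132 differed by 0.37 (SE 0.14, limma adjusted p = 0.251). Across alternatives this ranged from 0.064 to 0.63, with a limma adjusted p of 0.0671 to 0.894. Its 2 spots differed, at 0.28 (SE 0.25) and 0.57 (SE 0.14) for extended arrays against the mean of both other groups. Limma called 0 of 151 microRNAs, with 5 at an adjusted p under 0.1 and 25 at an unadjusted p under 0.05 (19 higher, 6 lower) where chance gives 7.55. For 47 microRNAs, or 31.1%, the groups did not overlap, beside the 10% that chance gives. Each group lay on its own slide, so slide and access cannot be told apart in either excess. Adjusted over the list alone, a list picked through the human arm of this series, miR-212 and miR-132 both passed (2 of 2), against 0 over all 151 probes. Next by unadjusted p came miR-369-5p at 0.32, miR-9 at 0.36, let-7d* at 0.29, miR-139 at 0.29 and miR-204 at 0.28.

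Of neuron-enriched microRNAs, 9 of 14 were higher with extended than restricted access and 7 had an unadjusted p under 0.05, miR-383 and miR-124a (-0.51) differing most. Adjusted over the list alone 4 of them passed, against 0 over all 151 probes. Camera's adjusted p for this list was 0.451, and 0.771 with an estimated correlation. Choroid plexus and ependyma microRNAs were positive in 3 of 3 (miR-204 at 0.28, miR-34c at 0.27), with a fry adjusted p of 0.0512, under 0.05 in 7 of 26 alternatives, and a camera adjusted p of 0.680 with an estimated correlation. The miR-379 to miR-410 cluster had 12 of 20 positive (miR-369-5p, miR-323 at 0.25), microRNAs linked to cocaine 7 of 12 (miR-124a, let-7d*), and the let-7 family 5 of 9 (let-7i at -0.56, or -0.92 without extended replicate 2 and -0.37 without extended replicate 3, let-7d* at 0.29) with a median just above and a mean below 0. The miR-29 family had 1 of 4 positive (miR-29c at 0.19, miR-29c* at -0.13), with fry's direction opposite to its median and mean. In the miR-30 family 2 of 5 were positive (miR-30b at -0.32, miR-30d at -0.26), in the miR-17/92 clusters 1 of 7 (miR-93 at -0.29, miR-17 at -0.16) and among synaptic plasticity microRNAs 3 of 9 (miR-9 at 0.36, miR-26a at -0.31). The miR-92 probe, outside the miR-17/92 list, went the other way, at 8.93 to 8.99 (log2) on extended and 8.54 to 8.92 on restricted arrays. Oligodendrocyte microRNAs had 1 of 4 positive (miR-23a at 0.29, miR-338 at -0.27), vessel wall microRNAs 1 of 4 (miR-126 at -0.46, or -0.27 without extended replicate 3, miR-143 at -0.21) and microglia and leukocyte microRNAs 4 of 4 (miR-223 at 0.24, miR-21 at 0.17). The miR-146 probe, outside the microglia and leukocyte list, read 8.29 to 8.70 (log2) on extended and 8.52 to 8.64 on restricted arrays. MiR-223 rested on extended replicate 1, the difference being -0.12 without it, and was above background on 1 of 3 extended arrays. Among pairs too small to test, miR-451 and miR-16 differed by -0.06 and -0.05, and miR-194 and miR-192 by -0.23 and 0.09. Camera called 0 of 12 lists (2 at an unadjusted p under 0.05, smallest adjusted p = 0.214, and 0.680 with an estimated correlation) and fry called 0.

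Across all 3 groups, miR-212, miR-218 and miR-7 led limma's F test, with an adjusted p of 0.175 each. Limma called 0 of 151 microRNAs in that test, with 19 at an unadjusted p under 0.05 where chance gives 7.55. By the exact permutation F test 16 had an unadjusted p under 0.05 and 0 passed after adjustment (smallest adjusted p = 0.270). MiR-212 and miR-7 were the 2 microRNAs at the smallest p that test can give. The exact trend test put 3 microRNAs under 0.05 before and 0 after adjustment: miR-137, miR-352 and miR-422b, the last named after its values were seen.

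The human arm asked which transcripts differed when cells of a human embryonic kidney (HEK) line overexpressed miR-212. In the authors' deposited table, 92 of 18859 probe sets with an empty vector signal of at least 100 were at least 2-fold higher with miR-212 (0.488%) and 238 were at least 2-fold lower (1.26%). That filter looks at the empty vector array alone and so leaves out probe sets that were dim there and bright with miR-212. With a signal of at least 100 in at least 1 array, 228 were higher and 238 lower in the authors' deposited table, and with no filter 467 and 525. The first of these filters could not change the lower count. A set under 100 with empty vector and 2-fold lower with miR-212 stays under 100 in both arrays. The median log2 ratio in the authors' deposited table was 0.0026, with 2.5 and 97.5 percentiles of -0.83 and 0.68. Among the 18859 probe sets, the highest ratios in the authors' deposited table were 16.3, for a probe set going from 281 with empty vector to 4572 with miR-212, and 10.6, from 116 to 1224. The lowest among them in the authors' deposited table were 0.160, from 167 to 27, and 0.186, from 206 to 38. Of the array's own control sets named for ISGF3A, 2 went from 365 to 1345 and from 111 to 408 in the authors' deposited table, ratios of 3.69 and 3.66. The others, with an empty vector signal under 100, went from 15 to 118 and from 9 to 9 in the authors' deposited table, ratios of 7.95 and 1.08. By the authors' deposited table, GAPDH control sets had ratios of 1.07 to 1.13, and actin sets 1.08 at the 3' end, 1.396 in the middle and 1.73 at the 5' end. Spiked-in Bacillus transcripts had a median ratio of 0.518 over 17 sets in the authors' deposited table, and hybridisation controls 0.973 over 18 sets. Probe sets with an empty vector signal of 100 to 200 were at least 2-fold higher in 43 and lower in 85 of 3500 in the authors' deposited table, against 7 and 25 of 6916 at a signal of at least 1000. Each condition had 1 array, so these ratios compare those 2 arrays and have no replicate check.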

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

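All tests in this part were chosen after the results were seen.

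In the authors' deposited table, 631 HEK probe sets outside the submitters' filter had a signal over 100 with miR-212, in data that the comparison of the 2 conditions leaves out. Their median ratio was 1.51, so many lay near the filter, while 24 were at least 10-fold higher in the authors' deposited table and the largest ratio was 554. Their empty vector signals were all under 100, and large ratios over such dim signals are not exact folds. A control set named for ISGF3A was among those outside the filter, at 15 with empty vector and 118 with miR-212 in the authors' deposited table (ratio 7.95).

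Counting probe sets under 20 in one array and over 200 in the other, 15 were dim with the empty vector and bright with miR-212, and 0 the other way round. The median log2 ratio over probe sets above 100 in both arrays was 0.0132, so no common scaling difference was left among them. If the submitters' processing had set both arrays to a common level, that value was fixed beforehand. It then decides nothing about scaling before that step. Spiked-in Bacillus transcripts had a median ratio of 0.518 over 17 sets, and hybridisation controls 0.973 over 18 sets. Noise of dim probe sets would give both directions, and the reverse direction held 0% of the forward count, but with 1 array per group and signals near the floor this excludes nothing. A difference between the 2 cultures other than miR-212 cannot be told apart from an effect of miR-212, since the arrays per group numbered 1. An effect of the expressed miR-212 itself stays open as untested.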

How the results depend on the processing

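Only the alternatives with first or second spots, rat-probe, log2-scale and control-free quantile normalization, median scaling, numbered probes and flagged spots were chosen after the data were seen. For extended against control, limma called 0 microRNAs under each of the 27 alternatives. For restricted against control it called 75 without normalization and 69 with the value table, neither of which scales arrays to a common brightness, and 0 to 10 when single arrays were left out (10 without control replicate 1). For extended against restricted it called 1 after 75th percentile scaling and 1 after median scaling (miR-212 in both), 2 with eBayes's trend and robust options (miR-212 and miR-7) and 0 to 0 when single arrays were left out. The F test called 1 after 75th percentile scaling (miR-212), 1 with the value table (miR-494) and 0 to 0 with arrays left out. Camera called 0 to 1 lists for extended against control with arrays left out, the 1 being the miR-29 family without control replicate 3 (adjusted p = 0.0335, and 0.618 with an estimated correlation), and 0 in the other 2 comparisons under every alternative run. The fry adjusted p of the choroid plexus list for extended against restricted ranged from 0.00235 to 0.331 and was under 0.05 in 7 of 26 alternatives: 0.00327 with no filter on dim probes, 0.0473 with second spots, 0.0127 after median scaling, 0.04999 with quantile normalization on the log2 scale, 0.0108 without control replicate 1, 0.00236 without control replicate 2 and 0.00235 with only the 6 arrays of both groups. The unadjusted exact permutation p of miR-212 over the groups lay between 0.00357 and 0.0278 in the 25 alternatives (0.00357 to 0.00714 with arrays left out). Adjusted over the 4 tests it was under 0.05 in 24 of them. Unadjusted, its exact trend p became 0.00357 without normalization and 0.00357 with the value table (0.250 to 0.725 with arrays left out). The unadjusted exact permutation p of miR-132 ran from 0.0357 (without restricted replicate 3) to 0.193 with arrays left out, and its trend p was 0.0417 after 75th percentile scaling, 0.0417 without normalization, 0.0417 with the value table, 0.0214 after median scaling (0.0429 adjusted, the only alternative under 0.05 once adjusted) and 0.0607 to 0.193 with arrays left out. With the replicate number as a block, extended against restricted gave 1 call (miR-383, adjusted p = 0.00625), the F test 1 (miR-383) and the miR-132 trend an exact p of 0.0278 (0.0556 adjusted over the 4 tests). The exact permutation p of miR-212 was then 0.0278, the smallest the blocked F test can give, and 0.0556 adjusted, so that call ended. No other call changed. Whether the numbers pair the arrays is not settled. Same-numbered arrays of different groups deviated together with correlations of -0.15 to 0.50, over 0.1 in 5 of 9 pairs. Arrays with different numbers from different groups did so with correlations of -0.54 to 0.31. Probe sets at least 2-fold higher and lower in the authors' deposited table numbered 467 and 525 with no filter, 228 higher with a signal of at least 100 in at least 1 array, 48 and 74 over 200 in both arrays, and 789 and 1275 at 1.5-fold. Where the setting itself does not show it, the cause was not tested. Signal over background limits the tests to 151 of 237 probes. Not run were the pixel mean, probes named for rat alone (the set already used), the slide as a block (each group had its own), HEK ratios per gene and the HEK gene lists; the trend option had no bearing on permutation or list tests.

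Of 2604 alternative values of 97 named differences, 118 turned. Of these, 71 came from the 4 settings that scale whole arrays differently or not at all (no normalization, the value table, 75th percentile and median scaling). Against the quantile normalized values, these settings did not move all differences of a comparison alike. After median scaling, for extended against control, miR-192 rose from -0.0048 to 0.045 while miR-451 fell from 0.07 to -0.063. The other 47 turned values came from 27 differences, and 70 differences kept their direction in the remaining settings. Past the threshold only in an alternative were 45 values of 20 differences, 17 for restricted against control and 3 for extended against restricted. Turned log2 differences without normalization were for extended against control miR-29b 0.10, miR-29a 0.0079, miR-30b 0.013, miR-20a 0.12, miR-23b 0.18, miR-16 0.24, miR-24 0.20, miR-145 0.18, miR-194 0.047, miR-192 0.30, for restricted against control miR-212 0.26, miR-218 0.13, miR-222 0.24, miR-664 0.21, miR-29c 0.27, miR-29a 0.19, miR-30a-3p 0.27, miR-25 0.35, miR-9 0.31, miR-223 0.021, miR-150 0.43, miR-204 0.23, miR-34c 0.21, miR-192 0.37, and for extended against restricted miR-23a -0.033, miR-21 -0.017, miR-192 -0.074. With the value table they were for extended against control miR-29b 0.10, miR-29a 0.0079, miR-30b 0.014, miR-20a 0.15, miR-23b 0.18, miR-16 0.24, miR-24 0.20, miR-145 0.24, miR-194 0.10, miR-192 0.34, for restricted against control miR-212 0.27, miR-218 0.13, miR-222 0.25, miR-664 0.27, miR-29c 0.30, miR-29a 0.19, miR-30a-3p 0.32, miR-25 0.40, miR-9 0.32, miR-223 0.050, miR-150 0.44, miR-204 0.25, miR-34c 0.32, miR-192 0.42, and for extended against restricted miR-23a -0.033, miR-21 -0.017, miR-192 -0.081. After 75th percentile scaling they were for extended against control miR-93 -0.018, miR-125b -0.00093, miR-223 -0.12, miR-451 -0.12, miR-34c -0.026, for restricted against control miR-132 -0.027, miR-494 -0.21, miR-125b -0.066, miR-451 -0.32, miR-16 -0.071, miR-194 -0.14, and for extended against restricted miR-451 0.19. With first spots they were for extended against control miR-383 0.024, miR-382 0.22, miR-23b 0.11, miR-223 -0.027, miR-194 0.31, miR-192 0.037, for restricted against control miR-150 0.046, miR-16 -0.28, and for extended against restricted miR-30d 0.015, miR-16 0.24. With second spots they were for extended against control miR-93 -0.029, miR-16 0.019, for restricted against control miR-132 -0.12, miR-329 -0.23, miR-25 0.0015, miR-194 -0.25, and for extended against restricted miR-143 0.044. After median scaling they were for extended against control miR-223 -0.063, miR-451 -0.063, miR-192 0.045, for restricted against control miR-451 -0.094, and for extended against restricted miR-451 0.032. The deposited matrix, quantile normalized, gave for extended against control miR-223 -0.070, miR-204 -0.0041, and quantile normalization over rat probes gave for restricted against control miR-132 -0.069. With single arrays left out, the ranges that crossed 0 were for extended against control miR-29b -0.34 to 0.019, miR-93 -0.12 to 0.27, miR-219 -0.051 to 0.26, miR-23b -0.22 to 0.13, miR-223 -0.28 to 0.28, miR-21 -0.017 to 0.18, miR-451 -0.080 to 0.31, miR-16 -0.11 to 0.15, miR-145 -0.17 to 0.030, miR-204 -0.036 to 0.10, miR-192 -0.13 to 0.15, for restricted against control miR-132 -0.031 to 0.19, miR-16 -0.066 to 0.17, miR-192 -0.22 to 0.058, and for extended against restricted miR-338 -0.45 to 0.076, miR-223 -0.12 to 0.44, miR-451 -0.21 to 0.060, miR-16 -0.13 to 0.11. Without crossing 0, a further 37 moved by over 1.5 times when an array was left out, with ranges for extended against control miR-212 0.32 to 0.59, let-7f 0.22 to 0.46, miR-222 -0.37 to -0.18, miR-382 -0.46 to -0.14, let-7c 0.36 to 0.69, let-7b 0.19 to 0.51, miR-29a -0.13 to -0.062, miR-30d 0.018 to 0.41, miR-20a -0.25 to -0.049, miR-125b 0.061 to 0.36, miR-24 -0.10 to -0.022, miR-34c 0.013 to 0.21, miR-194 -0.20 to -0.043, for restricted against control miR-124a 0.31 to 0.78, miR-30d 0.28 to 0.67, miR-329 0.14 to 0.46, miR-29c -0.28 to -0.13, miR-29a -0.13 to -0.062, miR-30a-3p -0.31 to -0.081, miR-93 0.18 to 0.57, miR-25 -0.27 to -0.0024, miR-125b 0.15 to 0.45, miR-219 0.14 to 0.50, miR-223 -0.23 to -0.024, miR-150 -0.33 to -0.0091, miR-451 0.0080 to 0.37, miR-143 0.11 to 0.34, miR-34c -0.26 to -0.082, miR-194 0.021 to 0.19, and for extended against restricted miR-323 0.16 to 0.33, let-7i -0.92 to -0.37, miR-29c* -0.22 to -0.016, miR-30b -0.46 to -0.16, miR-23a 0.19 to 0.38, miR-126 -0.58 to -0.27, miR-194 -0.30 to -0.15, miR-192 0.052 to 0.13.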

Other observations

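The tests against probes of like brightness, of single spots, of slides, of negative control spots, of local background, of median scaling and of other splits were chosen after the results were seen, while the comparison without normalization was planned.

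The higher miR-212 and miR-132 on extended arrays stood out from probes of like brightness. Among the 30 probes nearest to each in mean intensity, both lay at percentile 100 for extended arrays minus the mean of the other groups (0.61 for miR-212 and 0.42 for miR-132). Both were known to be high on extended arrays when this test was chosen, so a high rank was likely beforehand. The rank therefore cannot decide on a slide difference that depends on brightness. An artefact of 1 spot was argued against for miR-212, where the smaller of its 2 spot differences was 4.25 standard errors. For both microRNAs together it stays open, since the first spot of miR-132 gave 1.10 standard errors. Any other difference between slides cannot be told apart from cocaine access, because 0 slides held over 1 group, and an effect of extended access stays among the open explanations.

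Restricted arrays were brighter before normalization, with 151 of 151 microRNAs higher than in control arrays and 75 past limma's threshold, all of them higher. The negative control spots shifted by 10.4% of the shift of the detected probes. Those spots were measured after background correction, so they say little about the background itself. The median local background of rat spots was 85 to 86 on control and 81 to 83 on restricted arrays, which argues against a higher background. After each array was scaled to its median the number past the threshold was 0, but such scaling removes a common shift whatever its origin, so this decides nothing. Whether the brightness came from the slide, the labelling or the amount of small RNA in the tissue was not tested, and each group lay on its own slide.

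The counts of microRNAs past limma's threshold were set against other splits of the same arrays. For each of the 3 pairwise comparisons the 10 possible splits are too few for a share under 0.05. The real count was 0 in each, with the highest other split at 3 for extended against control and 0 for the other comparisons, and 10 of 10 splits gave as many, as any split must when the real count is 0. For the F test over the 3 groups, 100 of the 280 splits were drawn, 100 gave at least the real count of 0 and the highest other was 3. A count of 0 is reached by every split, so these comparisons say nothing about chance.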
